A study of Mus musculus with 3 samples.

How the data were processed

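Gene expression was measured on 1-colour Affymetrix-type arrays in RAW264.7 cells, a mouse macrophage line, at 0, 2 and 12 h of lipopolysaccharide (LPS), the outer membrane component of Gram-negative bacteria that Toll-like receptor 4 recognises. There was 1 array per time and 3 arrays in all. Per the labels' protocols, total RNA was extracted with a commercial kit and the hybridisation target was made from 5 µg of it by a modified Affymetrix procedure. The LPS dose, the scanner software and the array normalization are not given in the sources used here.

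The authors deposited linear probe set intensity values for 22690 probe sets, 64 of them controls, with no detection calls. All deposited values were positive. The 2% trimmed mean was 150.05 at each time, so the arrays had been scaled to one target before deposit. The deposited medians were 56.3 at 0 h, 51 at 2 h and 54.4 at 12 h. Values are therefore relative to the trimmed mean of each array, and a change in the total amount of mRNA would not be seen.

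Of the probe sets, 20393 had 1 gene in the platform annotation supplied with the data, 691 had several genes and were not used, and 1606 were not listed and stay unnamed. Gene identifiers were looked up in a RefSeq gene table of assembly GRCm38.p6, where 20364 matched. That table was used for names only, and no genome coordinates are given because no build belongs to the array values. After controls were set aside, 12393 genes remained, 4956 of them with more than 1 probe set. Where a gene had several probe sets, the one with the highest mean log2 signal over the 3 arrays was used.

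Each array was rescaled to a common 2% trimmed mean over the non-control probe sets, which moved values by less than 1%. A floor was set at the 40th percentile of all scaled values, a signal of 34.96, and values under it were set to it before log2 was taken. A gene under the floor on both arrays of a comparison has no fold. A gene under it on 1 array has only a bound, written as "at least". The number of arrays limits the precision: with 1 array per time there was no replicate and no test of the conditions, no p-value was computed, and a gene is called higher or lower when its signals differ at least 2-fold.

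As the only error the arrays hold, a measure chosen after the data were seen, the spread between probe sets of one gene was computed over genes with several probe sets above the floor. The SD of the log2 difference between probe sets was 0.32 for 2 h against 0 h, 0.34 for 12 h against 0 h and 0.31 for 12 h against 2 h. It leaves out what all probe sets of a gene share, such as differences between cultures or a shift of a whole array. Unchanged genes were also simulated 100 times, with a noise SD per signal bin taken from the median absolute deviation of the observed differences, which assumes normal noise. That SD came only from genes above the floor on both arrays, so it may be off for genes near or under the floor.

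A total of 20 gene lists and 8 lists of markers of other cell types were fixed before the data were examined, as were the floor, the size that counts, the alternatives and the rule for named genes. For each list with at least 5 measured genes, the median log2 difference was set against the medians of 10000 random lists of the same size matched on mean signal in 20 bins, as a description of these arrays. The named genes were, for each time against 0 h, the 10 largest increases and 10 largest decreases above the floor on both arrays, the 5 largest bounds in each direction, and up to 4 members per list. For 12 h against 2 h, the 5 largest in each direction were named. Genes in opposite directions at the 2 times were named too, and Gapdh, Actb, Tlr4, Tnf, Nos2 and Il1b always. A gene with probe sets at least 2-fold in opposite directions was left out of these ranks, which applied to 1 gene in the comparison of 12 h with 2 h and to none in the others. Other members of a list are named as examples, chosen after their values were seen.

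The alternatives were the deposited values without rescaling, median scaling, quantile normalization, floors at the 20th and 60th percentiles, a pseudocount in place of the floor, the median over a gene's probe sets, probe sets without a cross-hybridisation suffix, and folds of 1.5 and 3. A count was taken as moved when it went beyond 1.5 times the count reported, and a list median or gene when it moved by more than the SD between probe sets. The counting was tested on simulated data in which the 12 h array was made from the 0 h array with a noise SD of 0.25 and 50 of the 12393 genes changed at each of 4 fold sizes, in 10 runs. It called 99.4% of genes raised 4-fold, 100% of genes raised 8-fold, 44.2% of genes raised 2-fold and 81% of genes lowered 4-fold. Of unchanged genes it called 0.44%. In each changed gene only the brightest probe set was altered. In a gene with several, an unchanged probe set could then be read in its place, which can reduce the rate for lowered genes. How much of the 81% depends on this was not tested. The changed genes were drawn only from those of middle signal at 0 h, well above the floor, and the noise was the same at every signal. The rates for changed genes therefore say nothing about genes near or under the floor. A list of 30 genes shifted by 1 log2 unit lay at percentile 100, and 1 of 20 random lists fell outside the central 95%. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.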

Results

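To follow the transcriptional response of macrophages to LPS, expression was profiled in RAW264.7 cells before treatment and after 2 and 12 h of LPS. Each time was represented by 1 array, without replicates, and no untreated array at 2 or 12 h is in the design, so every difference from 0 h holds time in culture as well as LPS. Of 12393 named genes, 8115 were at or above the floor at 0 h, 7811 at 2 h and 8171 at 12 h, and 3654 were under it on all 3 arrays. Signals below are linear and scaled, and every fold compares 2 arrays. Differences between arrays varied among probe sets of one gene with an SD of 0.31 to 0.34 on the log2 scale. The error between cultures was not measured.

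After 2 h of LPS, Cxcl2, a neutrophil chemokine gene, had the largest increase among genes above the floor on both arrays. It was 65.3-fold higher than at 0 h (signal 3459 against 53), and Il1b, which encodes interleukin 1 beta, was 46.8-fold higher (1968 against 42.1). Nfkbiz, an atypical IkB protein, was 34.2-fold higher, Cd83 22.4-fold, Gadd45b 19.7-fold, Ccl5 18.4-fold and Tnf 18.2-fold (3346 against 184). By the median over its 3 probe sets, Gadd45b had a log2 difference of 2.70 in place of 4.30. Tnfaip2 was 12.8-fold, the zinc finger factor Egr2 12.2-fold and Myc 11.1-fold higher. Among genes under the floor at 0 h, Acod1, the enzyme that makes itaconate, was at least 72.8-fold higher (2546 against 10.2), the cytokine signalling inhibitor Socs3 at least 27-fold, the kinase Pim1 at least 24.9-fold, Lif at least 20.6-fold and Phlda1 at least 18-fold. By the median over their probe sets, the log2 differences were 3.80 for Socs3, 3.76 for Pim1 and 3.38 for Lif. By the brightest probe set these were 4.76, 4.64 and 4.37. Sizes over a low 0 h signal depend on the floor: with it at the 60th percentile the log2 difference was 5.35 in place of 6.03 for Cxcl2, 4.54 in place of 5.55 for Il1b and 4.91 in place of 6.19 for Acod1.

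Decreases at 2 h were smaller. Mtss1 was 4.67-fold lower (38.5 against 180), although the median over its 3 probe sets was a log2 difference of -0.45. Pom121, a nuclear pore protein, was 3.97-fold lower, the sialyltransferase St8sia4 3.77-fold and Txnip, which binds thioredoxin, 3.71-fold. By the median over its 2 probe sets, Pom121 had a log2 difference of -1.19 in place of -1.99. Tifa was 3.27-fold, Calhm2 3.25-fold, Fos 3.20-fold, Tlr4, the LPS receptor, 3.06-fold (82.2 against 251), Lzts2 2.98-fold and Rab3il1 2.97-fold lower. Id2, an inhibitor of helix-loop-helix factors, was at least 7.12-fold lower. Depdc7 was at least 3.53-fold, Olfr1508 at least 3.32-fold, Ppargc1b at least 3.21-fold and Neurl4 at least 3.13-fold lower. Tifa, Calhm2, Lzts2, Rab3il1 and these last 4 genes were under 2-fold with the floor at the 60th percentile.

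In all, 176 of 8422 measured genes were at least 2-fold higher at 2 h and 142 were at least 2-fold lower. Increases of at least 4-fold numbered 58 and decreases of that size 2. Unchanged genes, simulated in the settings reported alone, gave a mean of 29.9 higher and 28.9 lower, with a highest count of 47 and 42. The number of decreases depended on the scaling: with arrays set to one median, which shifted the median of genes above the floor on both arrays from -0.10 to 0.04 on the log2 scale, 225 genes were higher and 73 lower. Under quantile normalization the split was 200 to 86. With the floor at the 20th percentile more genes were lower than higher, 510 against 350, and with a fold of 1.5 the numbers were 812 and 472. Of 101 genes at least 2-fold apart that had another probe set above the floor, the other probe sets went the same way for 91 and by at least 1.5-fold for 68.

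Of the 20 gene lists, 7 had a median above the central 95% of random lists at 2 h and 3 below it; at 12 h the numbers were 13 and 2. The list of NF-kB and feedback regulators stood highest, with a median log2 difference of 1.70 (random lists -0.27 to 0.07). Besides NF-kB subunits and inhibitors it holds other genes, such as Socs3, Dusp16 and Traf1, so its median does not measure NF-kB alone. Of its 22 measured members, 15 were at least 2-fold higher and none lower. Besides Nfkbiz, Socs3 and Tnfaip2, Traf1 was at least 15.8-fold higher, Rel 7.72-fold, the A20 gene Tnfaip3 6.78-fold and Nfkbia, the classical NF-kB inhibitor, 2.77-fold. Chemokines had a median of 1.11 (random -0.23 to 0.12), with 8 of 15 members higher and none lower, among them Cxcl10 at 10.5-fold and Ccl4 at 10.8-fold. The chemokine median was 0.33 with a pseudocount and 1.89 with the floor at the 60th percentile. Immediate early genes had a median of 0.93 (random -0.22 to 0.07). Of 28 members, 11 were higher, including Dusp2 at 9.13-fold and Ier3 at 9.56-fold, and 2 were lower, namely Fos and Jun, the latter 2.84-fold. Inflammatory cytokines had a median of 0.72 (random -0.25 to 0.11), with 7 of 17 higher and none lower; Csf3, the granulocyte growth factor, was at least 7.11-fold higher. With a pseudocount the cytokine median was 0.48.

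The secreted protease and matrix list had a median of 0.39 at 2 h (random -0.28 to 0.10), and 4 of 15 members were higher. These were Saa3 by 5.55-fold, Sdc4 by 4.13-fold, the urokinase receptor gene Plaur by 3.97-fold and Tgm2 by 2.62-fold. By the median over probe sets the log2 difference was 1.21 in place of 2.05 for Sdc4, and 0.87 for Tgm2. The list's median was 0.20 with a pseudocount and 0.58 with suffixed probe sets left out. Cholesterol synthesis genes had a median of 0.26 (random -0.24 to 0.10), with 3 of 20 at least 2-fold higher, namely Hmgcs1 at 2.44-fold, Sc5d at 2.27-fold and Cyp51 at 2.06-fold. Sc5d and Cyp51 were under 2-fold by the median over their probe sets, with log2 differences of 0.54 and 0.86, and Cyp51 also with a pseudocount, at 0.96. The list's median was 0.40 with median scaling. The list of nitric oxide, prostaglandin and oxidant enzymes had a median of 0.19 (random -0.17 to 0.14), with 4 of 18 higher; these were Acod1, the prostaglandin synthase gene Ptgs2 at 9.9-fold, the cystine transporter gene Slc7a11 at 3.85-fold and Gch1, which supplies the nitric oxide synthase cofactor, at 2.22-fold. The log2 difference of Gch1 was 0.98 by the median over its probe sets and 0.99 with a pseudocount. The median of this list was 0.33 with median scaling and 0.095 with a pseudocount, and it was inside the random range with the floor at the 60th percentile. Nos2, read by 1 probe set, had signals of 5.1, 3.4 and 5.01 at 0, 2 and 12 h, under the floor on every array. Whether that probe set detects Nos2 was not tested, so these values cannot show whether the gene changed.

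The 3 lists below the random range at 2 h had small medians. Cell cycle genes had a median of -0.18 (random -0.15 to 0.08), or -0.038 with median scaling, with Cdc6 2.88-fold and Ccne2 2.05-fold lower and the cyclin-dependent kinase inhibitor gene Cdkn1a 2.23-fold higher. The log2 difference of Ccne2 was -0.89 with median scaling, -0.97 under quantile normalization and -0.86 with a pseudocount, all under 2-fold, and that of Cdc6 was -0.68 with the floor at the 60th percentile. Oxidative phosphorylation genes had a median of -0.11 (random -0.10 to 0.10) and ribosomal protein genes -0.12 (random -0.11 to 0.10); no member of either list was 2-fold apart, and both signs turned with median scaling, to 0.033 and 0.022. The ribosomal list was inside the random range under quantile normalization, with the median over probe sets and with suffixed probe sets left out. Lists inside the random range still held single genes with large differences. In the antigen presentation list (median 0.00), Cd83, Cd40 at 4.84-fold and the adhesion molecule gene Icam1 at 3.72-fold were higher. In the cell death list (median -0.05), Gadd45b, Tnfrsf1b at 3.04-fold, Gadd45a at least 3-fold and Bcl2l11 at 2.82-fold were higher. In the stress response list (median -0.01), Hspa1b was at least 4.77-fold, Herpud1 3.62-fold and Sqstm1 2.33-fold higher. Gadd45a and Hspa1b were under 2-fold with the floor at the 60th percentile. In the Toll-like receptor list (median 0.03), Tlr2 was 2.20-fold higher and Tlr4 lower. The interferon response list had a median of -0.10 (random -0.26 to 0.05), and only Oasl1 at 5.42-fold and Ifih1 at 4.34-fold were at least 2-fold higher among 31 members. The remaining medians were 0.02 for lipid handling, 0.07 for glycolysis, 0.02 for lysosome and -0.11 for macrophage identity. In the macrophage list Clec4e was 2.90-fold higher, Tgfbr2 2.20-fold lower and Cd200r1 at least 2.09-fold lower. Neither decrease kept 2-fold under every alternative: the log2 difference of Tgfbr2 was -0.76 by the median over its probe sets and -0.996 with median scaling, and that of Cd200r1 was -0.99 under quantile normalization and -0.93 with a pseudocount.

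**Figure D1:**
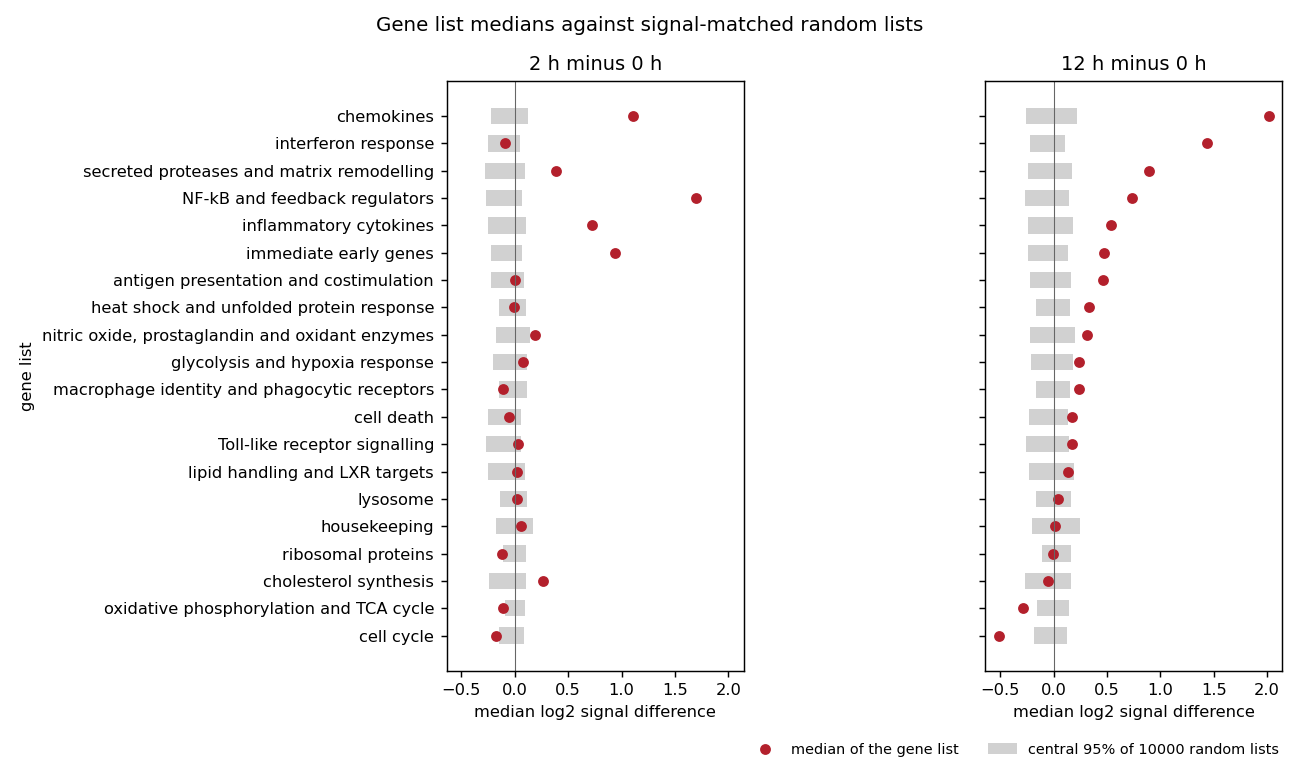
Median log2 signal difference of each gene list (red points, x axis) at 2 h against 0 h (left) and 12 h against 0 h (right), with 1 array per time; grey bars give the central 95% of 10000 random lists of the same size matched on signal. The NF-kB list lies at 1.70 at 2 h and 0.74 at 12 h, while the interferon response list lies at -0.10 at 2 h and 1.43 at 12 h.

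After 12 h of LPS, Cxcl2 was 69.9-fold, Il1b 62-fold and Ccl5 43.9-fold higher than at 0 h, and Acod1 was at least 73.2-fold higher. Saa3, an acute phase protein gene, was 16.3-fold higher, Pdpn, which encodes podoplanin, 16.2-fold (587 against 36.4), and Il1rn, the interleukin 1 receptor antagonist gene, 15.3-fold (2994 against 196). Zbp1, a nucleic acid sensor gene, was 12.7-fold, the chemokine gene Ccl3 11-fold, the peptide transporter gene Slc15a3 10.8-fold and the chemokine gene Ccl7 10.8-fold higher. At 2 h, Pdpn, Il1rn and Ccl7 had been less than 2-fold over 0 h, while Saa3 and Slc15a3 had been 5.55-fold and 2.79-fold higher. Csf3 was at least 32.7-fold, Socs3 at least 26.1-fold, Lcn2, the siderophore-binding lipocalin gene, at least 18.2-fold and Il1a at least 13.6-fold higher. By the median over its probe sets, Socs3 had a log2 difference of 4.08 in place of 4.70. Sizes over a low 0 h signal depended on the floor here too. With it at the 60th percentile the log2 difference was 2.93 for Saa3, 2.79 for Pdpn and 2.52 for Zbp1. In the settings reported these were 4.03, 4.01 and 3.67.

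Among genes above the floor on both arrays, the largest decreases at 12 h were in Plau, the urokinase gene, 8.85-fold lower (40.4 against 357), and the ribonuclease gene Rnase4, 6.32-fold lower. The log2 difference of Plau was -2.47 in place of -3.15 by the median over its 2 probe sets. With the floor at the 60th percentile it was -2.08 for Plau and -2.19 for Rnase4. Ndrg2 was 4.07-fold, Pom121 4.04-fold, Psrc1 3.98-fold and the mitotic cyclin gene Ccnb2 3.91-fold lower (199 against 776). The log2 difference of Pom121 was -1.16 in place of -2.02 by the median over its 2 probe sets. Itga6 was 3.61-fold, St8sia4 3.56-fold, the centromere histone gene Cenpa 3.56-fold and Adssl1 3.48-fold lower. Cd24a was at least 5.78-fold, Frmd4b at least 4.07-fold, Rab3il1 at least 3.35-fold, Olfr1508 at least 3.32-fold and Hint2 at least 3.24-fold lower. Itga6, Frmd4b, Rab3il1, Olfr1508 and Hint2 were under 2-fold with the floor at the 60th percentile.

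At 12 h, 260 of 8629 measured genes were at least 2-fold higher and 207 were at least 2-fold lower, against means of 29.8 and 29.3 among simulated unchanged genes. Increases of at least 4-fold numbered 67 and decreases of that size 6. With a pseudocount in place of the floor, the split was 197 to 99, and with a fold of 1.5 more genes were lower, 893 against 718. Of 132 called genes with another probe set, 117 had it in the same direction and 79 by at least 1.5-fold.

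Interferon response genes were higher as a group at 12 h, with a median log2 difference of 1.43 (random -0.22 to 0.11). At least 2-fold higher were 20 of 34 measured members, and none was 2-fold lower. Besides Zbp1, the regulator gene Irf7 was 6.20-fold higher (1268 against 204), Oasl1 5.87-fold, the exonuclease gene Isg20 5.63-fold, Bst2 5.52-fold, the ISG15 protease gene Usp18 5.39-fold, Ifit3 5.31-fold, Ifit1 4.98-fold and Rsad2 4.82-fold. Mx1 stayed under the floor on all arrays. Against 2 h, 21 of 34 were at least 2-fold higher at 12 h and the median was 1.18.

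Chemokines had a median of 2.02 at 12 h (random -0.26 to 0.22), with 8 of 15 higher and none lower. The median depended on how low signals were treated and was 0.86 with a pseudocount. Inflammatory cytokines had a median of 0.54 (random -0.24 to 0.18), with 6 of 18 higher. The median was 1.07 and 1.85 with the floor at the 20th and 60th percentiles, and the lowest under any alternative was 0.36. The secreted protease and matrix list had a median of 0.90 (random -0.24 to 0.17), with 11 of 23 higher, including Mmp9 at 6.51-fold, Serpinb2 at least 10.5-fold and Lcn2, and only Plau lower; its median was 0.54 with a pseudocount. The NF-kB list had a median of 0.74 (random -0.27 to 0.15), with 9 of 22 higher. Among them were Nfkbiz at 9.53-fold, Traf1 at least 6.09-fold and Dusp16, with signals of 237 at 12 h and 79.1 at 0 h. Immediate early genes had a median of 0.47 (random -0.23 to 0.14), with 6 of 26 higher, among them Ier3 at 10.2-fold, Myc at 9.02-fold, Cebpd at 3.05-fold and Zfp36 at 2.96-fold; their median was 0.28 with a pseudocount. Antigen presentation genes had a median of 0.47 (random -0.22 to 0.17), with 4 of 21 higher: Cd40 at 6.21-fold, Cd274 at 2.97-fold, the peptide transporter gene Tap1 at 2.10-fold and Tapbp at 2.07-fold, or a log2 difference of 0.67 by the median over the probe sets of Tapbp. Tap1 was at 0.90 with a pseudocount, and Cd274 at 0.55 with the floor at the 60th percentile. The stress response list had a median of 0.33 (random -0.16 to 0.16), with Dnajb9 2.31-fold, Sqstm1 2.24-fold, Ddit3 2.15-fold and Dnajc3 2.05-fold higher and Atf6 2.22-fold lower. With a pseudocount Ddit3 was at 0.72 and Atf6 at -0.91 on the log2 scale, both under 2-fold.

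Nitric oxide, prostaglandin and oxidant enzymes had a median of 0.32 at 12 h (random -0.22 to 0.20), with 8 of 19 higher and 1 lower. Acod1, Ptgs2 at 9.43-fold, Slc7a11 at 6.98-fold and Gch1 at 4.25-fold led the increases, and Gclc, a glutathione synthesis gene, was 2.62-fold lower. Macrophage identity genes had a median of 0.24 (random -0.17 to 0.15), with 8 of 29 higher and 3 lower; the median was 0.13 with the median over probe sets, and inside the random range with a pseudocount. The chemokine receptor gene Ccr1 was at least 8.56-fold higher and the Fc receptor gene Fcgr1 2.48-fold higher. Cx3cr1 was 2.00-fold and Tgfbr1 2.34-fold lower, the latter with a log2 difference of -0.95 under a pseudocount. Trem2 was 3.46-fold lower by its brightest probe set, whereas its probe set without a cross-hybridisation suffix gave a log2 difference of 0.24, so its direction is uncertain. Glycolysis genes had a median of 0.24 (random -0.21 to 0.19), with the glucose transporter gene Slc2a1 2.71-fold higher and Ndrg1 2.04-fold lower, or a log2 difference of -0.36 by the median over its probe sets. Cell death genes had a median of 0.17 (random -0.23 to 0.13). Tnfrsf1b at 9.35-fold, Gadd45b at 7.28-fold and Bcl2l1 at 2.56-fold led the increases, and Pmaip1 was 2.75-fold lower. By the median over its probe sets, Gadd45b had a log2 difference of 1.11 in place of 2.86. The Toll-like receptor list had a median of 0.17 (random -0.26 to 0.15) with no member 2-fold apart, and was inside the random range with the median over probe sets; Tlr4 was 1.43-fold lower.

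Cell cycle genes were lower at 12 h, with a median of -0.51 (random -0.18 to 0.12). Of 39 measured members, 8 were at least 2-fold lower and none was 2-fold higher. These included Ccnb2, the mitotic kinase gene Plk1 at 2.34-fold, the kinase inhibitor gene Cdkn2c at 2.32-fold and the proliferation marker Mki67 at 2.26-fold. Oxidative phosphorylation genes had a median of -0.29 (random -0.15 to 0.14), with none of 40 members 2-fold apart. Cholesterol synthesis stood inside the random range at 12 h with a median of -0.05, as did lipid handling at 0.13, with Abca1 2.25-fold and Hilpda 2.30-fold higher. Abca1 had a log2 difference of 0.72 by the median over its probe sets, 0.85 with a pseudocount and 0.75 with the floor at the 60th percentile, and Hilpda 0.89 with a pseudocount and 0.88 with that floor, all under 2-fold. The lysosome list, at 0.05, had Lgmn 2.43-fold lower.

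**Figure D2:**
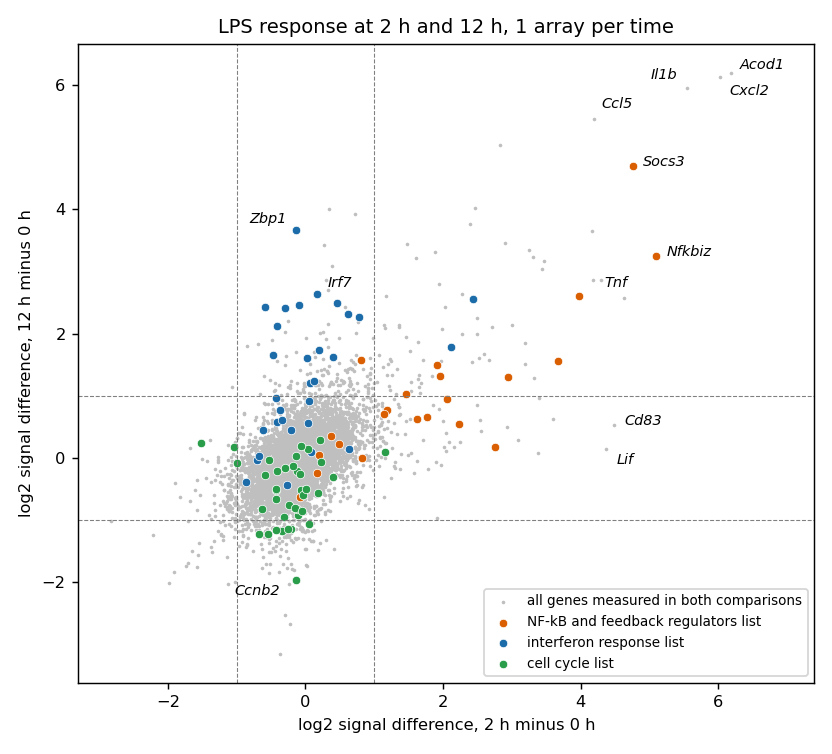
Log2 signal difference at 2 h against 0 h (x axis) and 12 h against 0 h (y axis) for each gene measured in both comparisons, with 3 gene lists in colour and dashed lines at 2-fold; both axes share the 0 h array. Interferon response genes such as Irf7 and Zbp1 lie high on the y axis near 0 on the x axis, and Cd83 and Lif lie far right near 0 on the y axis.

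By time pattern, 100 genes were at least 2-fold higher than at 0 h at 2 h alone, 76 at both times and 183 at 12 h alone. Lower genes numbered 109 at 2 h alone, 32 at both and 175 at 12 h alone. The size threshold sets these classes, and only the direct comparison of 12 h with 2 h speaks to a difference between the later times: 224 of 8467 genes were at least 2-fold higher at 12 h than at 2 h and 168 lower, or 178 and 226 with arrays set to one median. The count of 76 compares with 5.51 for independent lists and a mean of 2.88 in the simulation with a shared 0 h array. The count of 32 compares with 3.54 and 3.34. The simulation holds unchanged genes alone, with a mean of 29.9 called higher at 2 h, and neither number is the overlap of lists of the observed size that share an array. Both comparisons use the same 0 h array, which cannot be split, so the counts at the 2 times are not independent.

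Between 2 and 12 h, Lif was 18.7-fold, Cd83 15.4-fold, the transcription regulator gene Tsc22d1 9.78-fold, Egr2 7.87-fold and Pdgfb, a growth factor gene, 6.94-fold lower. Their 12 h signals were less than 2-fold over those at 0 h, or over the floor for Lif. By the median over its probe sets, Lif had a log2 difference of -3.31 in place of -4.22. Cxcl10 was 5.38-fold, Tnfaip3 6-fold and Icam1 3.90-fold lower. Among genes above the floor on both arrays, the largest increases were in Pdpn at 12.8-fold, Il1rn at 9.27-fold, Ccl7 at 9-fold, Usp18 at 8.09-fold and Procr, the protein C receptor gene, at 6.55-fold. Of genes under the floor at 2 h, Lcn2 was at least 18.2-fold, Zbp1 at least 13.9-fold and Serpinb2 at least 10.5-fold higher at 12 h. The NF-kB list had a median of -0.58 between 2 and 12 h (random -0.16 to 0.22), with 8 of 22 at least 2-fold lower. Immediate early genes had a median of -0.43 (random -0.15 to 0.18), with 5 of 28 lower. Cholesterol synthesis genes had a median of -0.34 (random -0.18 to 0.20). Acod1, Ptgs2, Ier3, Socs3 and Cxcl2 differed by less than 1.1-fold between 2 and 12 h.

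**Figure D3:**
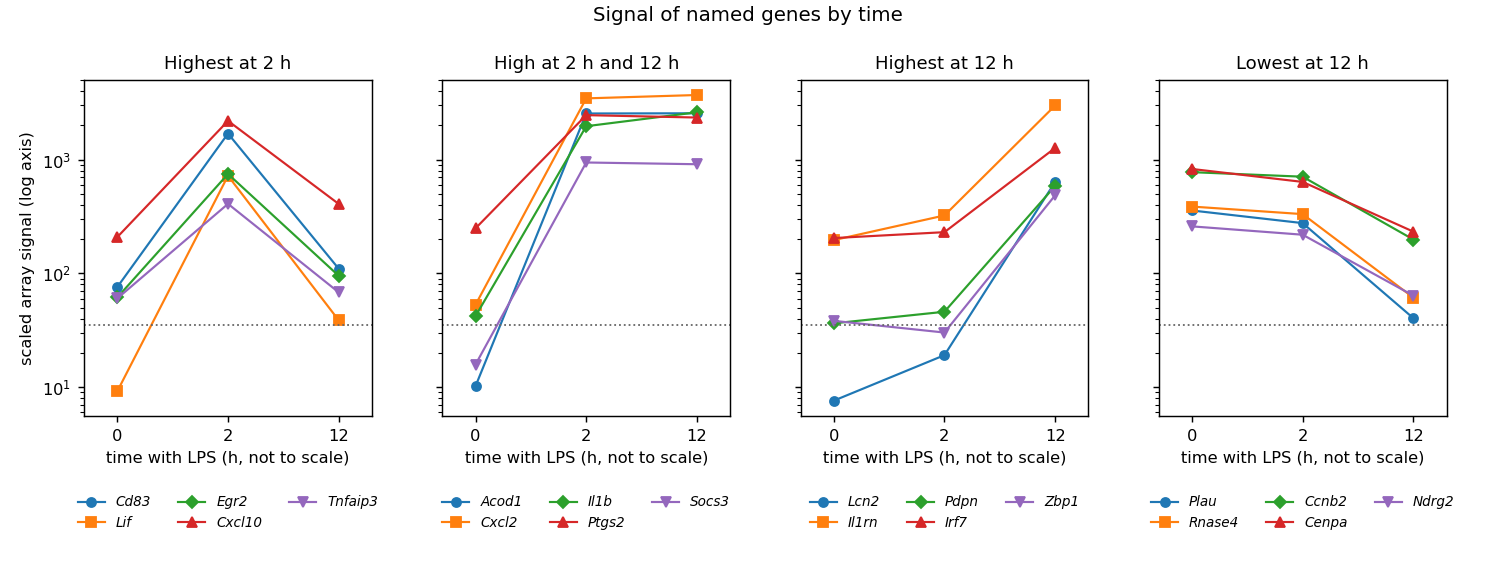
Scaled array signal (log axis) at 0, 2 and 12 h, 1 array per point, for 4 sets of 5 genes; the dotted line is the floor, and points under it have no order. Cd83 reaches 1695 at 2 h and 110 at 12 h, Acod1 holds 2546 and 2558, Il1rn goes from 323 to 2994, and Plau from 277 to 40.4.

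For some lists near 0 the median and the mean differed in sign. At 2 h these were interferon response (mean 0.04), lipid handling (-0.03), lysosome (-0.04), cell death (0.31), stress response (0.11) and housekeeping (-0.0040). At 12 h they were cholesterol synthesis (0.04), ribosomal proteins (0.01) and housekeeping (-0.03).

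As reference genes, the housekeeping list had medians of 0.06 at 2 h and 0.01 at 12 h, inside the random ranges, and ribosomal protein genes had a median of -0.01 at 12 h. Actb was 1.13-fold and 1.14-fold higher at 2 and 12 h by its brightest probe set. By the median over its 2 probe sets the log2 difference at 2 h was -0.32 in place of 0.17, so its direction there is uncertain. For 12 h against 2 h it was 0.78 in place of 0.02. The control probe set for the 3′ end of Gapdh had signals of 3700, 3603 and 4276. The ratio of 3′ to 5′ signal was 0.71, 0.66 and 0.68 for Gapdh and 1.11, 0.98 and 1.08 for Actb, where it was read as a measure of RNA integrity. For 18S rRNA the ratio was 2.85, 4.25 and 4.22, and for the transferrin receptor 2.72, 2.89 and 2.52. The pyruvate carboxylase control was under the floor at its 3′ end on every array.

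Markers of other cell types were mostly under the floor. At 0, 2 and 12 h, 1, 1 and 1 of 9 T cell markers passed it, with Zap70 at 359, 305 and 261. Of 7 B cell markers, 3, 3 and 4 passed, of 9 fibroblast markers 2, 1 and 1, of 7 epithelial markers 2, 1 and 2, and of 7 endothelial markers 2, 2 and 2. Of 9 neutrophil markers, 3, 2 and 6 passed, with only Lcn2 at least 2-fold higher at 12 h, and of 7 dendritic cell markers 3, 3 and 5, with Itgax 3.46-fold higher at 12 h. Of 7 osteoclast markers 4, 5 and 5 passed. Their median at 12 h was 0.74 (random -0.53 to 0.45), and Mmp9 and Acp5, the latter at least 2.02-fold higher, were the members past 2-fold.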

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

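Both tests on the spike-in controls were chosen after their values had been seen. Cd200r1, an inhibitory receptor gene of myeloid cells, was picked out because its 2 differences from 0 h have opposite signs. Its log2 difference was -1.06 at 2 h, a bound since the 2 h signal of 21.9 was under the floor, and 1.14 at 12 h (161 against 73). With a pseudocount the 2 were -0.93 and 0.86, and under quantile normalization the first was -0.99, all under 2-fold. Against 2 h, Cd200r1 was at least 4.62-fold higher at 12 h, a log2 difference of 2.21, or 0.93 with the floor at the 60th percentile. With 1 array per time this difference could not be tested, and the gene has 1 probe set.

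The hybridisation controls, bacterial and phage transcripts added to the labelled target, were looked at because they lie outside the comparisons of genes. At 12 h the signal over that at 0 h was 2.95 for bioB, 2.67 for bioC, 2.61 for bioD and 1.97 for cre. For the 18S rRNA control it was 2.53 by the 3′, 1.71 by the 5′ and 1.32 by the middle probe set.

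Across the 14 bioB, bioC and bioD probe sets the 12 h signal was 2.77-fold over 0 h and all 14 were higher, while at 2 h the ratio was 0.97. More spike-in mix on the 12 h array is a candidate explanation, and the SD of the 14 log2 differences, 0.27, is near one common factor, but cre was higher by less and reached 7451, close to the highest signal of the array. Less labelled cell target, raised again by the scaling, would also give one factor. It could raise the background too, and the 10th percentile of all probe sets at 12 h over that at 0 h was 1, but the lowest signals are not background alone. The 2 explanations cannot be told apart here, and no biological explanation was tested.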

How the results depend on the processing

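All alternatives reported here were planned. The deposited values without rescaling are almost those used, say nothing about stability and are left out of the tallies of counts and lists. Of the counts of genes apart under the other alternatives, 25 stayed within 1.5 times the count reported and 29 did not, and of the counts by time pattern 35 did and 37 did not. Of 259 medians of lists outside the random range in the settings reported, 2 changed sign, and of 161 medians of lists inside it, 29 did. In size, 16 list medians moved by more than the SD between probe sets. Of 223 differences of at least 2-fold among 114 named genes, 161 stayed at least 2-fold under every alternative that gave a value. The other 62 did not under at least 1 alternative. A gene without a value under an alternative, such as Procr with suffixed probe sets left out, was not counted as lost there. In size, 295 log2 differences of named genes moved by more than the SD between probe sets under the alternatives other than the deposited values. Apart from these, 2 differences of at least 2-fold changed sign, and the other 2010 moved by less than that SD. Sign changes of differences under 2-fold were not counted. Among them, by the median over probe sets, were Actb at 2 h, from 0.17 to -0.32, and Pdgfb at 12 h, from 0.29 to -0.14. No replicate could be left out, since each time has 1 array. The floor and the pseudocount act on genes with low signal over background, and the fold sizes change the bar itself. Scaling moved counts too, as it shifts whole arrays against each other. At 2 h the median log2 difference of genes above the floor on both arrays was -0.10 in the settings reported. It was 0.04 with median scaling and -0.05 under quantile normalization. Why the array medians differed was not tested.

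With arrays scaled to one median, 73 genes were lower at 2 h, and by time pattern 51 were lower at 2 h alone and 21 at both times. Medians at 2 h changed sign for oxidative phosphorylation, to 0.033, and ribosomal proteins, to 0.022, among lists outside the random range. Among lists inside it they did so for interferon response, to 0.049, macrophage identity, to 0.029, cell death, to 0.090, and stress response, to 0.13. With quantile normalization, 86 genes were lower at 2 h, 65 at 2 h alone, 21 at both times, and 0 lower then higher. With suffixed probe sets left out, Trem2 changed sign, to 0.24 at 12 h against 0 h and 0.17 against 2 h. With the median over probe sets, the chemokine median at 12 h was 1.49.

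With the floor at the 20th percentile, higher and lower genes were 350 and 510 at 2 h, 551 and 493 at 12 h, and 607 and 344 at 12 h against 2 h. By pattern, 168 were higher at 2 h alone, 181 at both and 366 at 12 h alone, and 367, 139 and 353 were lower. Lower then higher were 4, and higher then lower 1. Cytokine medians were 1.06 at 2 h and 1.07 at 12 h, the chemokine median at 12 h 0.97, and the protease median at 12 h against 2 h 0.39. With the floor at the 60th percentile, 52 genes were lower at 2 h, 171 higher and 113 lower at 12 h, and 126 higher and 111 lower at 12 h against 2 h. By pattern, 113 were higher at 12 h alone, 40 lower at 2 h alone, 12 lower at both, 101 lower at 12 h alone, and 0 lower then higher. Medians at 2 h were 1.89 for chemokines and 1.30 for the NF-kB list. At 12 h they were 1.85 for cytokines, 0.97 for chemokines and 1.01 for interferon response. At 12 h against 2 h they were 0.46 for cytokines and 0.34 for proteases.

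With a pseudocount, 44 genes were lower at 2 h, 99 at 12 h, and 139 higher and 99 lower at 12 h against 2 h. By pattern, 33 were lower at 2 h alone, 11 at both, 88 at 12 h alone, and 0 lower then higher. Chemokine medians were 0.33 at 2 h and 0.86 at 12 h, and protease medians 0.54 at 12 h and 0.22 against 2 h. With a fold of 3, higher and lower genes were 87 and 13 at 2 h, 101 and 27 at 12 h, and 55 and 48 at 12 h against 2 h. By pattern, 51, 36 and 65 were higher at 2 h alone, at both and at 12 h alone, 9, 4 and 23 lower, and 0 lower then higher. With a fold of 1.5 they were 472 and 812, 718 and 893, and 861 and 546, with 247, 217 and 487 higher by pattern, 503, 295 and 590 lower, 14 lower then higher and 8 higher then lower.

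Lists outside the random range in the settings reported stayed on that side under all 7 alternatives other than the deposited values, with some exceptions. Each was set against 2000 random lists. At 12 h, the Toll-like receptor and macrophage identity lists stayed there under 6. At 2 h, the nitric oxide, prostaglandin and oxidant list did so under 6 and ribosomal proteins under 4. At 12 h against 2 h, oxidative phosphorylation did so under 6 and the nitric oxide, prostaglandin and oxidant list under 4.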

Other observations

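The comparison of cell cycle phases was chosen after the result was seen. The tests on the interferon and cell cycle lists were set down before their medians were computed, but single genes of both lists had by then been seen among the largest differences. The rule for reading the Ifnb1 value was changed after that value was seen, and the outcome was undecided under either rule. The genes outside the fixed lists were also chosen after their values were seen.

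At 2 h, the receptor gene Gpr84 was 5.84-fold, the ubiquitin ligase gene Peli1 5.66-fold and Olr1, a scavenger receptor gene, at least 7.75-fold higher than at 0 h. The antioxidant gene Srxn1 was 3.20-fold higher at 2 h and 2.32-fold at 12 h. At 12 h, the surface receptor genes Clec4n, Ms4a6d and Pilra were 4.63-fold, 4.09-fold and 3.79-fold higher, and Lgals9, which encodes galectin 9, 4.06-fold. Usp2 was 2.94-fold lower at 2 h and 2.93-fold lower at 12 h, and Sesn1 2.59-fold and 2.68-fold lower. Of genes with known roles in mitosis that are not in the cell cycle list, Nusap1 was 2.96-fold, Kif2c 2.82-fold, Cenpf 2.75-fold and Ect2 2.60-fold lower at 12 h; how many others were lower was not counted.

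The interferon response list was higher at 12 h and inside the random range at 2 h. A shift of the whole 12 h array is argued against by the list's median, at percentile 100 among random lists matched on signal. Of the 20 members at least 2-fold higher, 16 were above the floor on both arrays. This count cannot decide on noise near the floor, since it includes Zbp1 and Isg20, both at 38.3 at 0 h against a floor of 34.96. With the floor at the 60th percentile the list's median was 1.01 in place of 1.43, still at percentile 100 among random lists. That argues against noise near the floor as the source of the whole median, but not for single members. An answer to interferon beta made by 2 h may contribute, but the value tested, at least 1.55-fold for Ifnb1 at 2 h with a signal of 54.1, is a bound, since the 0 h signal was under the floor, and whether it reached 2-fold is not known. That explanation stays open, and so does time in culture, which was not tested for this list.

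The cell cycle list was lower at 12 h, with its median at percentile 0 among random lists, which argues against a shift of the whole array. The median of 17 G2/M genes, -0.84, was below that of 16 G1/S genes, -0.14, a difference of -0.71 where random splits of these genes gave -0.54 to 0.52. At 2 h the order was the opposite, with -0.13 for G2/M and -0.36 for G1/S genes. A smaller share of cells in G2 and mitosis at 12 h may underlie part of the pattern, but this is a hypothesis that these values cannot decide, and DNA content was not analysed here. Time in culture could give the same median of -0.51, and without an untreated array at 12 h it and LPS cannot be told apart.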
